A study of Mus musculus with 2 samples.

How the data were processed

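Poly(A) RNA from G1E-ER4 cells treated with estradiol was sequenced in paired-end mode in 2 libraries, per the labels, which call them biological replicates 1 and 2. Both belong to 1 group. The labels do not say more on how the cultures were separated, so p-values carry no spread beyond these 2 libraries. For each library the authors deposited a gene table and a transcript table. Per the deposited description files, the values refer to the mouse assembly mm10 and GENCODE annotation M4. The aligner, the quantifier and their versions are not given in the sources used here.

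The deposited expected counts are estimated fragment counts per gene or transcript, which need not be whole, per the file headers. The deposited TPM values are, per the file headers, counts divided by effective length and scaled to the same sum in every library. The deposited FPKM values are fragments scaled by transcript length and library size, per the file headers. The transcript tables also hold the authors' deposited percent of a gene's TPM that each transcript takes. Posterior mean values are given beside these. The bounds of the TPM intervals in the files come with no stated level and were not used for any test. Genes that share sequence with close copies share reads through the estimation, which can move values within a family, and strand handling is not given in the sources used here.

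The 43346 gene rows were used. Another 26248 rows named by a number only and 97 spike-in rows, which held 0 counts, were left out of the tests. Names, gene types, coordinates and transcript GC content came from GENCODE M21 on the same build, whose gene models may differ from those used by the authors. It matched 42462 gene rows, of which 21474 were protein-coding, and gave a GC content, the unweighted mean over annotated transcripts, for 99.9% of them. Genes without a match held 0.157% of the counts. Of 471 list entries fixed beforehand, 9 were not matched and were not analysed here, among them Hbb-b1, Hbb-b2, Trfr2, Epb49, Ahsp, Fam132b, Lnk and Emr1.

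Lists, pairs, isoform genes, tests and alternative settings were chosen before the data were examined. A list level was the median of mean log2(TPM + 1) and was placed among 10000 random lists of protein-coding genes. Gene pairs were tested with limma 3.58.1 on log2(TPM + 1) ratios within libraries, with the spread of each side moderated by squeezeVar along a trend over genes with at least 1 TPM, and Benjamini-Hochberg adjustment over the 25 pairs. The spreads of the 2 sides were combined as if independent, so the spread of the ratio itself did not enter. Folds on this scale understate the change of low genes. Expected counts were rounded to whole numbers for the count tests. Libraries were compared by an exact two-sided binomial test at the ratio of totals after TMM scaling in edgeR 4.0.16, over genes with at least 20 summed counts, with Benjamini-Hochberg adjustment. List shifts between libraries were placed among 10000 random lists matched on expression. The common dispersion came from edgeR with an intercept alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

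Genes named are the 15 with the highest mean TPM, the 3 highest members and the lowest member of each list, most genes of the pairs and most isoform genes, and the 5 protein-coding genes most increased and most decreased in replicate 2 with a mean of at least 100 counts that passed the binomial test. Where members tied for the lowest, some or all are named. Tpi1 and the genes of the trace signals were named after their values were seen. Alternatives were the pseudocount, a filter on low values, FPKM, posterior means, TPM without globin and mitochondrial genes in the total, other random lists, other count minimums, library totals or DESeq2 1.42.0 size factors, and leaving out each replicate. Matching on GC content and adjusting TPM for GC were added after the data were seen.

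The steps were tested on simulated data. For gene pairs, the limma step over 8420 genes called 100% of 50 pairs at each true log2 ratio of 1, 2 and 4, and 6% of 50 pairs without a difference. For library differences over 10470 genes, the binomial step called 100% of 50 genes at true folds of 2 and of 0.5, 84% at 1.25, 70% at 0.8, and 0.107% of unchanged genes. These simulated counts held counting noise alone, without the further spread between the real libraries. The 0.107% is therefore not an error rate for these data. Total expected counts were 73681318 and 56056404, and a count of 0 allows up to 3 counts. Intervals are exact at 95%, and intervals and floors cover counting error only.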

Results

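Poly(A) RNA was measured by paired-end RNA sequencing in G1E-ER4 cells, a mouse erythroid line that lacks its own functional Gata1 gene and carries the erythroid transcription factor GATA1 fused to the hormone-binding part of the estrogen receptor. The cells had been treated with 10 nM 17beta-estradiol, which activates the fusion protein, for 30 h. The series held 2 libraries, labelled as biological replicates 1 and 2 of 1 group, and no untreated library was analysed here. The design therefore gives the level of genes and gene groups in this state, ratios between genes within a library, transcript usage, and the difference between the replicates, but no effect of estradiol. The gene rows summed to 73681318 expected counts in replicate 1 and 56056404 in replicate 2. Values are TPM, the abundance of transcripts corrected for length and scaled to the same sum in each library, as mean ± SD with n = 2 unless each library is given, and coordinates are those of the mouse build mm10.

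Gata1 (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071, minus strand) had 2036 TPM in replicate 1 and 1608 TPM in replicate 2, from 265076 and 159152 counts. These reads were counted on the Gata1 gene model, and the values do not separate an introduced Gata1 sequence from the endogenous locus. Esr1 (chromosome 10, 4611593 to 5005614, plus strand), the mouse estrogen receptor alpha gene, had 1 count in replicate 1 and 6 counts in replicate 2. Esr2 had 0 counts in both libraries, where a count of 0 allows up to 3 counts, or 0.0407 and 0.0535 CPM (counts scaled by the library total).

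Adult globin messages were the largest of the gene groups measured. The 4 measured adult globin genes held 27.5% ± 1.09 of TPM and 10.5% ± 0.0307 of counts, and the ferritin subunits Ftl1 and Fth1 held 7.56% ± 1.39 of TPM and 4.15% ± 0.554 of counts. The genes Gm42418 and Gm26917, annotated as non-coding, held 2.25% ± 0.0356 of TPM and 4.39% ± 0.0424 of counts. They lie side by side on the plus strand of chromosome 17, at 39846958 to 39848788 and 39843013 to 39846341. The values do not show whether their reads came from transcripts of these genes or from other RNA that shares their sequence. The beta-like globin gene Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand) was highest, at 144036 ± 14450 TPM. It was followed by the alpha-like gene Hba-a1 at 81081 ± 19202 TPM, Ftl1 at 55976 ± 14172 TPM, Hba-a2 at 48961 ± 6622 TPM and Fth1 at 19608 ± 262 TPM. The other 10 of the 15 highest genes were Gm42418 and Gm26917, the histone genes Hist1h2ap and Hist1h2ao, the ribosomal protein genes Rpl28, Rplp1, Rpl18 and Rpl41, and the glycolytic genes Gapdh and Aldoa. They lay between 15512 ± 1149 TPM for Gm42418 and 4865 ± 1041 TPM for Aldoa, and the 15 genes together held 44.3% ± 1.06 of TPM. Ribosomal protein genes held 8.21% ± 1.36 of TPM, replication-dependent histone genes 2.97% ± 0.365, and mitochondrially encoded genes 0.257% ± 0.00287. These are shares of the RNA that passed poly(A) selection, and those of the histone genes in particular need not be their shares in the cells. Globin, histone, ferritin and ribosomal protein genes have near-identical copies that can share reads, so the split within each family is uncertain. At least 1 TPM was reached in both libraries by 8004 genes, of which 7570 were protein-coding, and 928 protein-coding genes reached 100 TPM in both.

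Gene lists fixed before the data were examined were placed among 10000 random lists of protein-coding genes of the same size, as a description of these libraries without a p-value. Of the 25 lists, 14 lay above all but 2.5% of random lists and none lay below all but 2.5% of them. Of the 14, iron handling and stress response were at percentiles 99.97 and 99.66, and the other 12 lay above every random list. The comparison includes silent genes, so a high call separates an expressed list from an average of expressed and silent genes. When random lists were drawn from expressed genes, the call was no longer made for iron handling (percentile 79.8), the red cell membrane (94.1), S phase (49.1), mitosis (50.5), cell cycle inhibitors (95.6) and stress response (19.8). In that comparison embryonic globins stood at 0.1. The progenitor, megakaryocyte, myeloid, mast cell, lymphoid, pluripotency, fibroblast, endothelial, estrogen and sex chromosome lists stood at 0.0 each. The lists kept their silent members there, so a list with many silent members falls low by construction. With genes under 1 TPM left out on both sides, myeloid markers were low (0.66). Embryonic globins (6.48), progenitor genes (50.7), megakaryocyte markers (14.9) and the estrogen list (78.9) were then not called. The remaining lists named had too few such genes for a value.

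Genes of hemoglobin production were high. The adult globin list had a median of 65021 TPM, and its lowest measured member, Hbb-bt, had 1096 ± 481 TPM. All 12 heme synthesis genes reached 1 TPM in both libraries, with a median of 112 TPM. The porphobilinogen synthase gene Alad had 1017 ± 267 TPM, the mitochondrial transporter gene Abcb10 434 ± 27.9 TPM and the ferrochelatase gene Fech 428 ± 101 TPM, while Alas1, the housekeeping form of the first enzyme of the pathway, was lowest at 2.30 ± 0.0849 TPM. Iron handling genes had a median of 22.0 TPM (percentile 99.97), led by Ftl1, Fth1 and the iron chaperone gene Pcbp1 at 1424 ± 106 TPM, and the mitochondrial iron importer gene Slc25a37 had 297 ± 39.0 TPM. Its lowest member was the iron regulatory protein gene Ireb2, at 1.35 ± 0.354 TPM. The embryonic globin list was not called (percentile 82.4): Hbb-bh1 had 6.16 ± 1.78 TPM, Hba-x 4.16 ± 1.26 TPM and Hbb-y 3.06 ± 0.502 TPM, while Hbb-bh2 and Hbb-bh0 had 0 counts.

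Red cell structure and enzyme genes were also high as groups, with wide differences between members. The membrane and skeleton list had a median of 27.4 TPM, and 23 of its 26 measured members reached 1 TPM in both libraries. The beta-spectrin gene Sptb had 977 ± 40.3 TPM, the adducin gene Add1 928 ± 200 TPM and Tmcc2 835 ± 135 TPM. The water channel gene Aqp1 was lowest, with 0 and 3 counts. Red cell enzymes and chaperones had a median of 105 TPM, led by the biliverdin reductase gene Blvrb at 4000 ± 103 TPM, Gpx1 at 985 ± 179 TPM and Sod1 at 548 ± 42.6 TPM, and Gstm5 had 0 counts.

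Erythroid transcription factors and cofactors had a median of 119 TPM, and 30 of 32 reached 1 TPM in both libraries. Zfpm1, which encodes the GATA1 cofactor FOG1, had 2894 ± 521 TPM. Gata1 had 1822 ± 303 TPM, which may include reads of the introduced sequence. The bridging factor gene Lmo2 had 728 ± 75.2 TPM, while Runx1t1 had 0 counts. The progenitor list was not called (percentile 95.5) and its members were split. Runx1 had 181 ± 17.6 TPM, Hhex 126 ± 13.8 TPM and Ikzf1 124 ± 10.3 TPM. The stem cell factor receptor gene Kit had 0.810 ± 0.0849 TPM, Myb had 0.150 ± 0.0141 TPM, and Hoxa9, Mecom, Rgs18, Flt3 and Hmga2 shared the lowest mean of 0.005 TPM. Erythropoietin signalling and survival genes had a median of 42.6 TPM, with Pim1 at 512 ± 21.2 TPM, Mcl1 at 511 ± 118 TPM and the pro-apoptotic gene Bbc3 at 505 ± 129 TPM. The lowest members, Bcl2a1a and Fas, had 0 counts. Autophagy and mitochondrial clearance genes had a median of 60.8 TPM, led by Gabarap at 674 ± 75.2 TPM, Lamp1 at 285 ± 68.0 TPM and Foxo3 at 276 ± 24.7 TPM, and Atg4a was lowest at 0.240 ± 0.141 TPM.

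Cell cycle genes were detected together with cell cycle inhibitors. The S phase list had a median of 14.1 TPM, with Rrm2 at 173 ± 67.1 TPM, Ccne1 at 150 ± 22.5 TPM, Slbp at 137 ± 20.3 TPM and Prim1 lowest at 0.680 ± 0.184 TPM. The mitosis list had a median of 16.3 TPM, which differed between the libraries, at a log2(TPM + 1) of 4.67 in replicate 1 and 3.41 in replicate 2, with Ccna2 at 485 ± 23.1 TPM, Ube2c at 383 ± 42.2 TPM, Cenpa at 295 ± 10.2 TPM and Ttk lowest at 0.460 ± 0.226 TPM. Cell cycle inhibitors had a median of 33.9 TPM, with Gadd45a at 335 ± 3.04 TPM, Cdkn1a at 174 ± 27.5 TPM and Cdkn2c at 156 ± 24.7 TPM, while Cdkn1c and Cdkn2b had 0 counts. Glycolysis genes had a median of 120 TPM, led by Gapdh at 8687 ± 3738 TPM, Aldoa and Ldha at 1348 ± 360 TPM, and Ldhb was lowest at 0.0300 TPM in both libraries. Stress response genes were led by Hspa8 at 369 ± 70.5 TPM, Ddit3 at 156 and 147 TPM in replicates 1 and 2 and Hsph1 at 121 ± 3.68 TPM, and Atf3 was lowest with 0 and 3 counts. Housekeeping genes had a median of 47.5 TPM, led by Gapdh, which the glycolysis list also holds, Actb at 745 ± 131 TPM and Rplp0 at 607 ± 40.1 TPM, while Hprt had 0.825 ± 0.488 TPM at a transcript GC content of 40.1%.

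**Figure D1:**
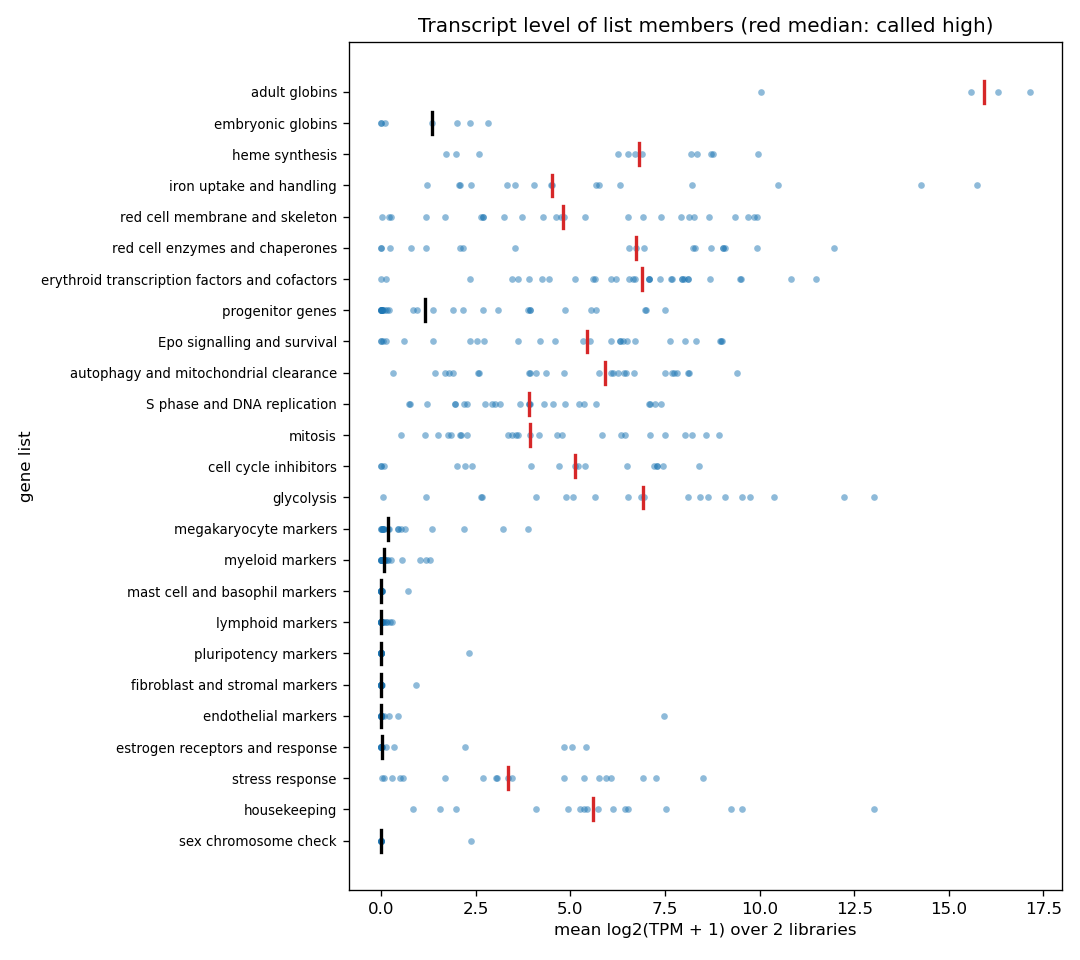
Each point is a measured gene of a list, placed on the horizontal axis by its mean log2(TPM + 1) over the 2 libraries, and the vertical bar is the list median, red where the list was called high. The adult globin list lies farthest to the right, with a median of 65021 TPM, and most genes of other cell types lie at or near 0.

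None of the lists of other cell types was called. Megakaryocyte markers (percentile 68.6) were led by Gp1ba at 14.2 ± 4.45 TPM, Tubb1 at 8.43 ± 2.52 TPM and Itga2b at 3.61 ± 0.516 TPM, and Clec1b had 0 counts. Myeloid markers (percentile 59.9) were led by the granule genes Mpo, Prtn3 and Elane, which were almost confined to replicate 2, at 3.96, 3.76 and 3.04 TPM against 0.19, 0.08 and 0.04 TPM in replicate 1. S100a8, Lyz1 and Ly6g had 0 counts. Mast cell markers (percentile 9.04) had Hdc at 0.640 ± 0.127 TPM as the highest member, then Mcpt1 at 0.015 ± 0.0212 TPM and Prss34 at 0.01 ± 0.0141 TPM. Lymphoid markers (percentile 8.29) had Lck at 0.225 ± 0.134 TPM, Cd79a at 0.175 ± 0.177 TPM and Pax5 at 0.115 ± 0.120 TPM. Pluripotency markers (percentile 13.1) had 1 member above 1 TPM in both libraries, Dppa4 at 4.05 ± 0.431 TPM, with Utf1, Nanog and Fgf4 at 0.005 TPM. Fibroblast markers (percentile 9.26) had Col5a1 at 0.930 ± 0.467 TPM, Col1a1 at 0.015 ± 0.00707 TPM, and Cxcl12 and Fn1 at 0.005 TPM. Endothelial markers (percentile 30.7) had Egfl7 at 178 ± 31.5 TPM, Ramp2 at 0.385 ± 0.276 TPM and Eng at 0.165 ± 0.0354 TPM. Members with 0 counts in both libraries included Cpa3 of the mast cell list, Cd3g of the lymphoid list, Pou5f1 of the pluripotency list, Col3a1 of the fibroblast list and Cdh5 of the endothelial list. The estrogen list (percentile 49.3) had Xbp1 at 42.2 ± 11.7 TPM, Esrra at 32.6 ± 7.16 TPM and Ncoa3 at 27.8 ± 0.495 TPM, while the classical estrogen target genes Tff1 and Pgr had 0 counts. In the sex chromosome list (percentile 9.99), Tsix had 4.21 ± 0.0495 TPM and Xist 2 and 10 counts, and Ddx3y, Uty, Kdm5d, Eif2s3y, Zfy1 and Sry had 0 counts in both libraries of a line labelled male.

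Ratios between related genes were taken within each library and tested with limma's moderated test on log2(TPM + 1). Of the 25 pairs fixed beforehand, 23 passed an adjusted p of 0.05, with the same sign in 2 of 2 libraries. The adjusted p-values rest on the moderated spread of each gene between these 2 libraries, with the 2 genes treated as independent. The spread of the ratio itself did not enter. Gata1 over Gata2 was 6.40 and 5.49 in the libraries with a standard error of 0.220. Klf1 over Spi1 was 6.83 and 6.78 with 0.181. Differences in GC content or mappability between genes are outside that error. The size of a ratio also depends on the pseudocount and on GC content: Ccnd3 over Ccnd2, reported at 7.42, was 4.22 after adjustment for GC, and Myb over Myc, reported at −5.48, was −7.65 with a pseudocount of 0.1 TPM. Adult exceeded embryonic beta-like globins by 13.81 ± 0.18 on the log2 scale (limma adjusted p = 1.08e-07) and adult exceeded embryonic alpha-like globins by 14.63 ± 0.64 (limma adjusted p = 1.08e-07). Adult alpha-like and beta-like globins were not separated, at −0.17 ± 0.44 with opposite signs in the libraries (limma adjusted p = 0.562). Gata1 exceeded Gata2 by 5.95 ± 0.64, Klf1 exceeded the myeloid factor gene Spi1 by 6.81 ± 0.03, Tal1 exceeded Lyl1 by 6.81 ± 0.12, Lmo2 exceeded Lmo4 by 7.34 ± 0.42 and Gfi1b exceeded Gfi1 by 7.37 ± 0.44. The largest limma adjusted p among these 5 pairs was 9.30e-07. Gata1 reads may include the introduced sequence, so the ratio to Gata2 need not be that of the endogenous genes. The erythroid Alas2 exceeded Alas1 by 6.62 ± 0.13, the anion exchanger gene Slc4a1 exceeded Kit by 8.49 ± 0.25, Slc25a37 exceeded Slc25a28 by 3.86 ± 0.14, Hk1 exceeded Hk2 by 6.89 ± 0.30 and Ccnd3 exceeded Ccnd2 by 7.42 ± 0.12. The largest limma adjusted p among these 5 pairs was 2.35e-06.

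Among survival and signalling pairs, Bcl2l1 exceeded Bcl2 by 8.19 ± 0.01 (limma adjusted p = 2.04e-07) but was below Mcl1, at −0.66 ± 0.32 (limma adjusted p = 0.0179). Bnip3l was below Bnip3, at −1.75 ± 0.08 (limma adjusted p = 0.000146). After TPM was adjusted for GC content, an alternative chosen after the data were seen, the last pair stood at −0.33 and Bcl2l1 over Mcl1 at −0.39, and neither passed (limma adjusted p = 0.154 and 0.134). Cdkn1b over Cdkn1a was not called at −0.16 ± 0.08 (limma adjusted p = 0.431), but the same adjustment put it at 2.95, in the other direction (limma adjusted p = 5.86e-06), and put alpha-like over beta-like globins at −1.72 (limma adjusted p = 0.00722). Tfrc exceeded Slc40a1 by 2.41 ± 0.06, Pklr was below Pkm at −2.14 ± 0.20, Myb was below Myc at −5.48 ± 0.27 and Stat5a was below Stat5b at −3.72 ± 0.01. The largest limma adjusted p among these 4 pairs was 8.52e-05. In 2 pairs the second gene was at or near 0, so no fold is given. Zfpm2 had 0 counts in both libraries beside Zfpm1, and Ank3 had 0 and 1 counts beside Ank1 at 409 ± 41.0 TPM.

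The transcript tables assigned most genes a leading transcript that was shared by the replicates. Among 3404 protein-coding genes with at least 10 TPM in both libraries and at least 2 annotated transcripts, 3085 (90.6%) had the same leading transcript, and the median share of that transcript was 74.7% in replicate 1 and 75.9% in replicate 2. Of the 30 genes fixed beforehand, the Gata1 transcript ENSMUST00000033502 held 99.97% of Gata1 in both libraries, the Zfpm1 transcript ENSMUST00000054052 held 99.4% ± 0.0283, the Nfe2 transcript ENSMUST00000075192 held 99.3% ± 0.198, the Pkm transcript ENSMUST00000034834 held 97.2% ± 0.764 and the Bcl2l1 transcript ENSMUST00000007803 held 96.6% ± 1.82. The Gata2 transcript ENSMUST00000015197, the Slc4a1 transcript ENSMUST00000006749, the Gfi1b transcript ENSMUST00000164290, the Sptb transcript ENSMUST00000166101, the Bcl11a transcript ENSMUST00000000881, the Mcl1 transcript ENSMUST00000178686, the Runx1 transcript ENSMUST00000168195 and the Cdkn1b transcript ENSMUST00000003115 held between 90.8% ± 1.91 and 96.2% ± 1.97. Klf1 and Epor had 1 annotated transcript, and all Kit reads were assigned to the Kit transcript ENSMUST00000005815, although the posterior mean share was 48.4% and 40.7%. The Mcl1 leader was short, with 858 bases against 3485 for ENSMUST00000037947, but had more counts, at 20652 and 21416 against 8154 and 9311. In other genes too the leader was short or annotated as non-coding. These shares are of TPM, which divides counts by length, so a short transcript can lead with fewer counts. The Alas2 transcript ENSMUST00000142474, a processed transcript of 569 bases, held 79.1% ± 0.686 of Alas2 against 14.6% ± 0.403 for the protein-coding transcript ENSMUST00000066337. The Pklr transcript ENSMUST00000151591, a processed transcript of 345 bases, held 71.2% ± 5.52, the Epb41 transcript ENSMUST00000146021, also annotated as processed, held 85.9% ± 2.72, and the Slc25a37 transcript ENSMUST00000184914, annotated as subject to nonsense-mediated decay, held 65.8% ± 4.64. The Tal1 transcript ENSMUST00000136946, of 683 bases, held 64.0% ± 2.38, and the Lmo2 transcript ENSMUST00000138815, of 478 bases, held 60.1% ± 1.58. The Pklr leader had 1222 and 869 counts, against 5984 and 2804 for the protein-coding ENSMUST00000047111. The Tal1 leader had 10767 and 7547 counts, against 26836 and 22668 for ENSMUST00000162489. For Lmo2 they were 11511 and 6974, against 11353 and 8172 for ENSMUST00000123437. The Alas2, Epb41 and Slc25a37 leaders had more counts than the transcript second in share. The Hk1 transcript ENSMUST00000072357 held 86.2% ± 1.53, the Foxo3 transcript ENSMUST00000175881 76.5% ± 8.51, the Slc11a2 transcript ENSMUST00000023774 66.1% ± 8.95, the Ank1 transcript ENSMUST00000118733 52.5% ± 6.55, the Alas1 transcript ENSMUST00000143125 44.9% ± 13.7 and the Tfrc transcript ENSMUST00000023486 35.9% ± 7.53. In replicate 2 the 166-base Tfrc transcript ENSMUST00000124243 was ahead of it, at 32.9% against 30.6%, on 5 counts.

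The replicates were similar in rank. Across 7867 expressed protein-coding genes, which are not independent replicates, Pearson's r was 0.988 and Spearman's rho 0.987, and 92.4% of genes lay within 1.5-fold. The coefficient of variation between the libraries was 18.8% from edgeR's common dispersion. The chi-square between their counts was 128 per degree of freedom, so the libraries do not hold identical counts, but this sets them against counting noise alone, without a spread of technical replicates to compare with. An exact two-sided binomial test, which compares these libraries and not conditions, called 6193 of 10445 genes, 3020 higher and 3173 lower in replicate 2. The balance of directions depended on scaling, with 2423 higher and 3776 lower under library totals and 3180 higher and 2989 lower under DESeq2 size factors, and 425 genes also differed by over 2-fold.

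Replicate 2 was lower in genes of glycolysis and of the cell cycle. Set against random lists matched on expression, the median log2 ratio of replicate 2 to replicate 1 was −0.43 for glycolysis, −0.42 for S phase, −0.38 for mitosis and −0.47 for housekeeping genes, each at percentile 0.0. Gapdh had 11330 TPM in replicate 1 and 6043 TPM in replicate 2, and Tpi1 had 1325 and 551 TPM. The most abundant cell cycle genes did not all follow their lists: Ube2c had 353 and 413 TPM, Ccna2 469 and 502 TPM, and Ccne1 134 and 166 TPM, and the summed TPM of the mitosis list was nearly equal, at 2150 and 2084. Heme synthesis (−0.29), iron handling (−0.23), the red cell membrane (−0.23) and embryonic globins (−0.21) were also lower. Erythropoietin signalling and survival (0.07), megakaryocyte markers (0.11) and myeloid markers (0.14) were higher. The iron and erythropoietin calls were lost when random lists were also matched on GC content (percentiles 2.71 and 96.7) and came back with wider expression bins tried afterwards (2.13 and 97.6), and the embryonic globin call was lost with a pseudocount of 0.1 TPM (3.62). The iron and megakaryocyte lists differed in sign between median and sum. The summed TPM of the iron list was higher in replicate 2, at 87448 against 67710, and that of the red cell membrane list was nearly equal, at 5192 against 5205. The megakaryocyte list had lower summed counts in replicate 2, at a CPM ratio of 0.720 (exact 95% interval 0.687 to 0.755), and without genes under 1 TPM the list stood at percentile 30.6 with a median of −0.16. The other 14 lists were not called.

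**Figure D2:**
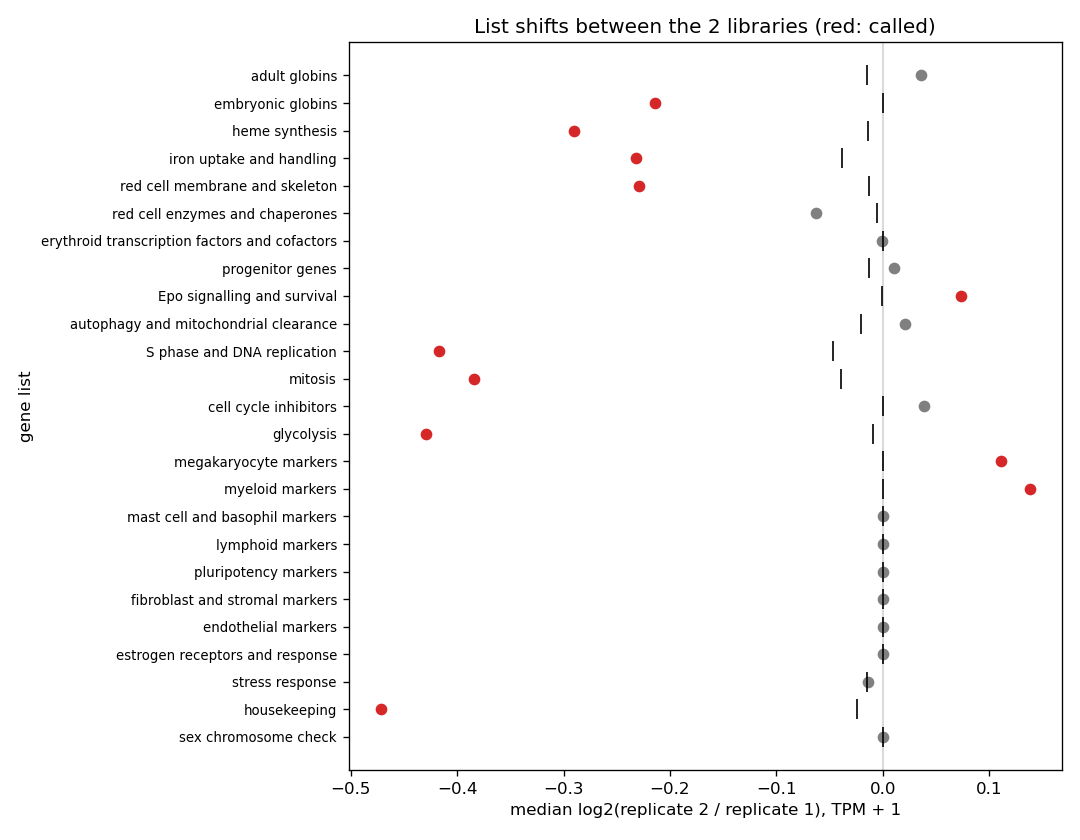
Each point is the median log2 ratio of replicate 2 to replicate 1 over a list, on TPM + 1, red where the list was called, and the short black line is the median of random lists matched on expression. Housekeeping and glycolysis lie farthest to the left, at −0.47 and −0.43.

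Among protein-coding genes with a mean of at least 100 counts that passed the binomial test, the 5 most increased in replicate 2 were Mpo (chromosome 11, 87793581 to 87804413, plus strand), with 32 and 507 counts, Trim17 with 101 and 293, Gm27029 with 73 and 175, Gm10073 with 376 and 856, and Gm11273 with 351 and 648. The 5 most decreased were Zbed5 with 227 and 22 counts, the splicing factor gene Srsf7 with 1051 and 113, Rpp14 with 295 and 42, the MHC class II invariant chain gene Cd74 with 182 and 26, and the ribosomal protein gene Rps28 with 41907 and 7112.

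Transcript level also differed along GC content, across genes that are not independent replicates. Among 7866 expressed protein-coding genes, Spearman's rho of level with GC content was 0.317, and within 6 protein complexes it ranged from −0.264 for ATP synthase to 0.831 for the proteasome.

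**Figure D3:**
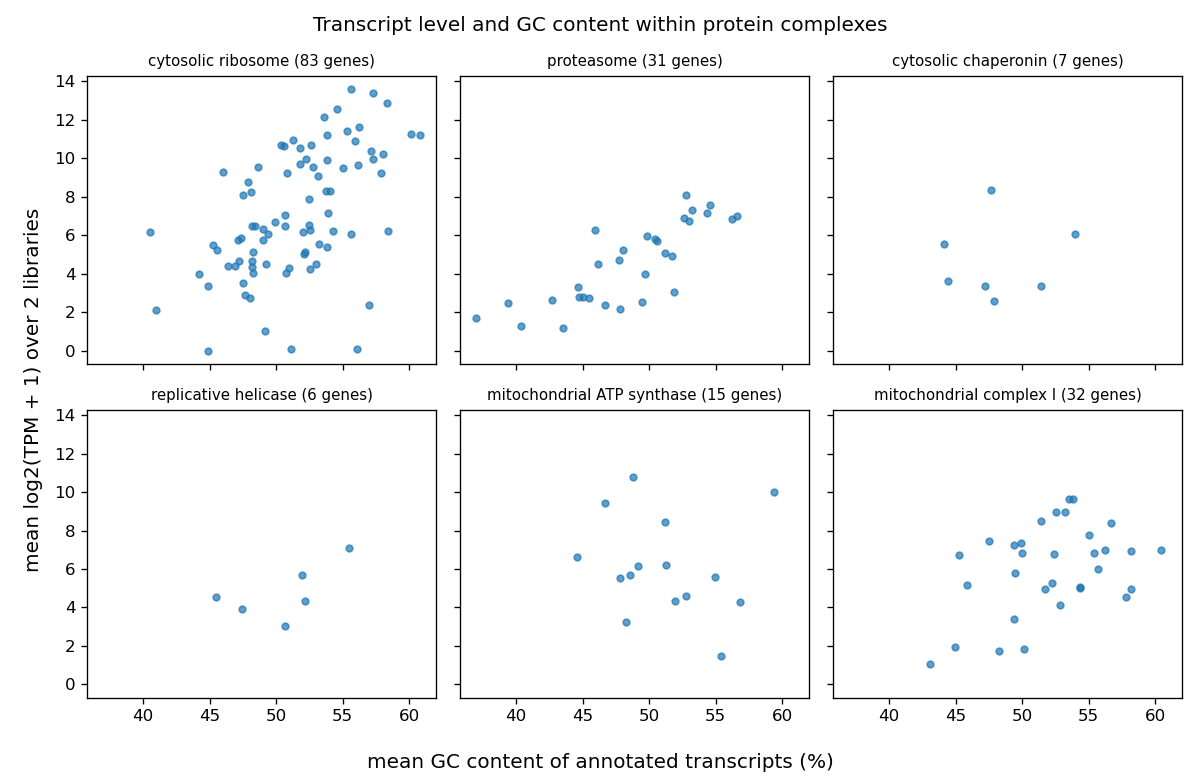
Each point is a gene of a protein complex, with the mean GC content of its annotated transcripts on the horizontal axis and its mean log2(TPM + 1) over the 2 libraries on the vertical axis. Level rises with GC content in the proteasome (rho 0.831) and the ribosome (0.557), and not in the chaperonin (0.0) or ATP synthase (−0.264).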

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

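The tests of transcript length, of the granule genes and of the shift between replicates were chosen after the results were seen, as were the restriction to protein-coding transcripts, the GC matching and the leaving out of single myeloid genes. The tests over complexes and over all transcripts of a gene were written before their results. Features named by a number only, which no comparison used, held 5 counts in replicate 1 and 4 counts in replicate 2, summed over 26248 rows. No explanation for these was tested.

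Transcript level rose with GC content across 7866 expressed protein-coding genes (rho 0.317), and detection rose from 12.5% of genes under 40% GC to 44.6% of those from 55% to 60% GC, with 37.5% above that. Transcript length is argued against as the whole cause, since the partial rho given length was 0.287, though this lies close to the bound of 0.9 times the unadjusted value. GC-dependent recovery of fragments may contribute: the median rho within 6 protein complexes was 0.389, above the 0.3 set beforehand, but only the proteasome (rho 0.831) and the ribosome (0.557) passed (permutation p = 0.0002, the smallest the permutations can give, adjusted p = 0.0006), complex I (0.293), the replicative helicase (0.486) and the chaperonin (0.0) did not, and ATP synthase had the opposite sign (−0.264). Within genes, the leading transcript was richer in GC than the others in 72.7% of 3362 genes, but retained introns and other non-coding transcripts can differ in GC for their own reasons, and with protein-coding transcripts alone the share was 62.3% of 2730. The ribosome set was gathered by gene name and includes paralogs such as Rpl39l, Rpl22l1 and Rpl3l, so its rho is not that of core subunits alone. No biological explanation was tested, and real differences in level between GC classes stay open.

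The granule genes Mpo, Elane and Prtn3 had 37 counts in replicate 1 and 818 in replicate 2, a CPM ratio of 29.1 (exact 95% interval 20.9 to 41.6), which argues against depth. Myeloid reads from another source may contribute, since the 19 other myeloid markers stood at 3.34 (2.39 to 4.73), with 15 members higher and 1 lower in replicate 2. The lower one, Cd68 (42 and 26 counts), held most of the counts in replicate 1, and without it the sum was 8 and 101 counts, at a ratio of 16.6 (8.11 to 39.5), whose interval overlaps that of the granule genes. Without Cd68 and the granule gene Ctsg the ratio was 13.1 (6.36 to 31.5), and leaving out any other single member gave 2.79 to 3.41. Transcripts abundant in mature neutrophils stayed low, with S100a8 at 0 counts, S100a9 at 0 and 3, and Lyz2 at 0 and 7. Some megakaryocyte markers, named after their values were seen, were also nearly confined to replicate 2: Pf4 had 0 and 20 counts, Gp1bb 1 and 43, and Vwf 0 and 24. The more abundant Gp1ba (3209 and 1504) and Tubb1 (952 and 470) were not. The excess was therefore not limited to myeloid genes, and no source was identified. Low expression in the cells themselves was not tested and stays open.

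Glycolysis and cell cycle lists had lower medians in replicate 2, although the summed TPM of the mitosis list was nearly equal (2150 and 2084) and Ube2c was higher. The shift was not particular to these lists: housekeeping genes had the largest (−0.47), and heme synthesis was also lower (−0.29). The log2 ratio of replicate 2 to replicate 1 did rise with GC content across genes (rho 0.177), and the S phase and mitosis lists had a lower median GC content (47.4% and 46.7%) than glycolysis (53.4%). GC-dependent recovery that differs between the libraries is argued against as the whole cause. Glycolysis and S phase stayed at percentile 0.0 among random lists matched on expression and GC. Mitosis had no value there and stood at 0.0 with the wider expression bins tried afterwards. For a later stage of differentiation in replicate 2, the red cell membrane list should have been higher, a test chosen after the shifts were seen. Its median log2 shift was −0.229, against that prediction, but its summed TPM was nearly equal (5205 and 5192). Globin genes were mixed: Hba-a1 was higher in replicate 2 (67503 and 94658 TPM) and Hbb-bs lower (154254 and 133818 TPM). A difference in stage therefore stays open. Growth state and handling of the cultures were not tested and stay open.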

How the results depend on the processing

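Matching on GC and adjusting for GC were chosen after the data were seen. With random lists from expressed genes, list levels stood at percentile 0.1 for embryonic globins, at 0.0 for progenitor, megakaryocyte, myeloid, mast cell, lymphoid, pluripotency, fibroblast, endothelial, estrogen and sex chromosome lists, 79.84 for iron, 94.11 for the red cell membrane, 49.08 for S phase, 50.54 for mitosis, 95.6 for cell cycle inhibitors and 19.84 for stress. Silent genes were left out of the random lists but kept in the lists tested, which accounts for this. With only genes of at least 1 TPM on both sides, list levels were 79.84 for iron, 49.27 for S phase, 58.42 for mitosis, 96.68 for cell cycle inhibitors, 0.66 for myeloid markers and 89.05 for stress. Embryonic globins (6.48), progenitor genes (50.69), megakaryocyte markers (14.88) and the estrogen list (78.92) stayed without a call. With posterior mean TPM, fibroblast markers stood at 1.61. All 25 lists kept their call with FPKM, a pseudocount of 0.1, GC-matched random lists and either replicate alone, although the mitosis median (log2 scale) was 3.41 without replicate 1 and 4.67 without replicate 2.

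For shifts between libraries, embryonic globins moved to 3.62 with a pseudocount of 0.1, 4.81 with only genes of at least 1 TPM and 4.94 with posterior means, and megakaryocyte markers to 30.61 with only genes of at least 1 TPM. With lists matched on expression and GC, iron moved to 2.71 and erythropoietin signalling to 96.74. That matching used narrower expression bins and gave no value for mitosis. Wider bins were therefore tried after these results were seen: they gave mitosis 0.0, and also brought iron to 2.13 and erythropoietin signalling to 97.61, back past the limits, so those calls depend on the bin width. Leaving out a replicate does not apply to shifts.

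Under GC adjustment, alpha-like over beta-like globins stood at −1.72, Bcl2l1 over Mcl1 at −0.39, Cdkn1b over Cdkn1a at 2.95 and Bnip3l over Bnip3 at −0.33. The adjustment used the slope within the 6 complexes, 0.312 log2 units per GC point (bootstrap 95% 0.234 to 0.395), which not every complex shares. The other 21 pairs kept their call but many changed in size, such as Ccnd3 over Ccnd2 from 7.42 to 4.22, Klf1 over Spi1 from 6.81 to 4.69 and Slc25a37 over Slc25a28 from 3.86 to 5.86. All 25 kept their call under FPKM, pseudocount 0.1 and posterior means, although a pseudocount of 0.1 moved Myb over Myc from −5.48 to −7.65. With only genes of at least 1 TPM, 18 of the 25 pairs had a value, and all 18 kept their call. Requiring over 2-fold left 425 library differences. Detected genes ranged from 5655 to 10265 under other minimums, and were 8118 without replicate 1 and 8306 without replicate 2. Except where stated, the cause was not tested. Counts near 0 limit ratios such as Zfpm1 over Zfpm2. No paired analysis was possible because there is 1 group.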

Other observations

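Low counts of antigen-presenting and B cell genes and of the chemokine gene Ccl22, chosen after their values were seen, were mostly lower in replicate 2, with exceptions. The choice shapes that majority, and these genes were not tested as a set. Cd74 had 182 counts in replicate 1 and 26 in replicate 2, Igha 128 and 0, Ccl22 141 and 0, Cd79a 29 and 4, Blnk 14 and 0, Cd79b 11 and 3, Pax5 7 and 2, and H2-Aa and H2-Eb1 6 and 1 each. Ighm (24 and 38) and H2-Ab1 (3 and 10) were higher in replicate 2, and Igkc (4 and 5) and Ebf1 (2 and 2) had too few counts to show a difference. The lymphoid list as a whole had 76 and 21 counts, a CPM ratio of 0.363 (exact 95% interval 0.213 to 0.595). The fibroblast list had 790 and 288 counts, of which Col5a1 alone held 777 and 283.

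The line is labelled male, and 5 Y-linked genes (Ddx3y, Kdm5d, Uty, Eif2s3y and Zfy1) had 0 counts in both libraries, while their X-linked homologs Ddx3x, Kdm5c, Kdm6a, Eif2s3x and Zfx summed to 34582 and 24516 counts. No explanation was tested.

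Subunits of the same complex differed in level along GC content in some complexes and not in others. In the proteasome, the median was 5.03 TPM for the 25% of genes lowest in GC and 136 TPM for the 25% highest, and in the ribosome 25.9 and 1209 TPM. The same medians were 22.8 and 118 TPM in complex I, 18.2 and 77.1 TPM in the replicative helicase, and 29.0 and 38.0 TPM in the chaperonin, where rho was 0.0. ATP synthase went the other way, with 71.5 and 33.2 TPM. The ribosome set was gathered by gene name and also held paralogs with low levels. On the log2(TPM + 1) scale, Rpl39l (44.9% GC) had 0, Rpl22l1 (41.0% GC) 2.13 and Rpl3l (56.1% GC) 0.104.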
